A study of Mus musculus with 10 samples.

How the data were processed

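Liver RNA was sequenced from 10 mice, 5 given AAV8-NC and 5 given AAV8-TBG-galectin-3, all on CDAHFD for 8 weeks. Groups and replicate numbers came from the sample titles. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads and made into strand-marked libraries by the dUTP method; the strand setting used in quantification is not given in the sources used here. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The genome build in those notes is a human build, GRCh38, while the gene identifiers in the deposited table are mouse Ensembl identifiers, so the mouse build and annotation are not known and no coordinates are printed.

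The deposited table held FPKM, fragments scaled to transcript length and library size, for each library, per the file headers. It also held the authors' own comparison: the deposited fold ratio, recomputed here as the ratio of group mean FPKM with a mean of 0 replaced by 0.0001, its log2 value in the deposited table, and the authors' p-value and q-value, whose test is not given in the sources used here. The authors' deposited mark of significance matched a q-value under 0.05 with at least a 2-fold change in every row. Of the 398 genes marked in the authors' deposited table, 8 were above 0 in only 1 library. All columns of sample values were used, and 0 pairs of libraries were identical.

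The plan written before the data were examined preferred a count model and named limma for FPKM; the file held no counts, so limma was the main test. The value of 1 fragment was read from the commonest low step of FPKM times length among genes with a single transcript, which gave 15.4 to 19.3 M fragments (M stands for 1e6) per library. The step was searched for only within a fixed window of values, which limited the depths that could be found. Only 10.8 to 13.0% of low values were whole multiples of that step, with a tolerance of 0.02, so whole reads were not recovered. FPKM carries no counting interval, so precision is given by the spread between the 5 mice of a group.

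Genes with an FPKM of at least 0.5 in at least 5 libraries were kept, 13471 in all. Values were taken as log2(FPKM + 1), with no further scaling, and the groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, no covariates, two-sided p and Benjamini-Hochberg adjustment, called at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Single values were compared by exact two-sided permutation of the labels. The interval of Lgals3 came from the moderated variance of the limma fit; an interval from that gene's own pooled spread had been computed first, was wider, and is printed beside it.

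Before the data were examined, 38 gene lists of pathways and liver cell types were fixed; 740 genes of the table matched their 761 symbols. The 35 lists with at least 5 tested members were compared with camera (preset correlation of 0.01), with camera at an estimated correlation, and with fry. With an estimated correlation 0 lists passed, and with fry 0 passed in 1 direction and 20 in either direction; 4507 single genes had an unadjusted limma p under 0.05. The named genes were, by a rule written before the data were examined, the galectins, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 FPKM, leaving out symbols of Gm and digits, symbols ending in Rik and genes without a symbol, and up to 4 called members of each list past its set test, or the 2 with the smallest p where fewer than 2 were called; about 30 are described, and some genes that the rule takes are not reported here.

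Transcript length and GC content were those of the longest transcript in GENCODE M21, matched by Ensembl identifier alone, for 97.9% of tested genes. The length trend was removed by fitting, in each library, a natural spline with 4 degrees of freedom to the departures from the gene means. The fit was tested on simulated data for this comparison with 13471 genes and 3 draws. In these, 64% of 300 genes changed 1.5-fold and 89.7% of 300 changed 2-fold were called, and 4.75% of the calls were false. The simulated folds were set on the log2(FPKM + 1) scale and the errors were independent between genes. Real genes were correlated (estimated correlation 0.56 in the cell cycle list), so these rates may not hold for the real data. No batch is given that separates the libraries, so no batch could be compared, and whether a batch moves with the groups is not known. Alternatives were other pseudocounts, filters, scalings, weights, variance moderation and thresholds, a replicate block, removal of length and GC trends, and leaving out each library in turn.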

Results

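The data were bulk liver RNA-seq profiles of 10 C57BL/6 mice kept for 8 weeks on CDAHFD, a diet rich in fat and lacking choline that is used to produce fatty liver with inflammation and fibrosis. The control group of 5 mice received AAV8-NC, a negative control adeno-associated virus. The other group of 5 mice received AAV8-TBG-galectin-3, which the labels name as a galectin-3 knockdown in hepatocytes; TBG is a promoter active in hepatocytes, and the labels do not describe the insert of the vector. Each library gave FPKM values for 29657 genes, with 21653 to 23079 genes above 0. The steps between low FPKM values corresponded to 15.4 to 19.3 M fragments per library, where M stands for 1e6, with 18.0 ± 0.934 M in the control group and 17.6 ± 1.88 M in the other (mean ± SD, n = 5 each). These depths are uncertain, because only 10.8 to 13.0% of low values were whole multiples of the step. Genomic positions are not given, because the mouse genome build behind the values is not given in the sources used here.

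The first comparison asked whether the targeted transcript, Lgals3 (ENSMUSG00000050335), which encodes the sugar-binding protein galectin-3, was lower in whole liver. Lgals3 stood at 70.8 ± 22.9 FPKM in the control libraries and at 74.2 ± 20.1 FPKM in the libraries labelled knockdown (SD, n = 5 each). The control libraries 1 to 5 held 105, 73.9, 61.6, 71.0 and 42.2 FPKM, and the labelled knockdown libraries 1 to 5 held 67.4, 90.8, 85.2, 85.6 and 41.9 FPKM. The log2 fold change was 0.08 with an SE of 0.25 (limma, adjusted p = 0.856), and an exact two-sided permutation test over the 252 assignments gave p = 0.794, where the smallest possible p was 0.00794. The 95% confidence interval from the limma fit ran from 0.722-fold to 1.54-fold, and an interval from the spread of this gene alone ran from 0.661-fold to 1.68-fold. A decrease of Lgals3 was therefore not detected in whole liver, which also holds Lgals3 from cells other than hepatocytes, and the sign of the small difference turned to -0.09 without control 5 and to -0.01 without labelled knockdown 2. Because the targeted gene did not follow the label, the group is called labelled knockdown throughout, and every direction given here rests on the labels.

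Of the 6 tested genes of the galectin list, Lgals3bp, which encodes a secreted glycoprotein that binds galectin-3, fell. It went from 42.7 ± 5.29 to 29.9 ± 5.02 FPKM (log2 fold change -0.51, SE 0.12, limma adjusted p = 0.0204), below the control mean in 5 of 5 labelled knockdown libraries. Leaving out control 3 raised its adjusted p to 0.0518. Lgals9 (log2 fold change -0.25, adjusted p = 0.0855), Lgals4 (0.58, 0.190), Lgals8 (-0.13, 0.246) and Lgals1 (-0.23, 0.420) did not pass the limma test. Lgals9 passed as lower in 4 of 11 alternative settings, among them removal of the length trend (adjusted p = 0.0471), and in 1 of the 10 fits without 1 library. Adjusted over the list alone, 1 member was lower and 0 were higher. The set test of the list gave an adjusted p of 0.458.

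**Figure D1:**
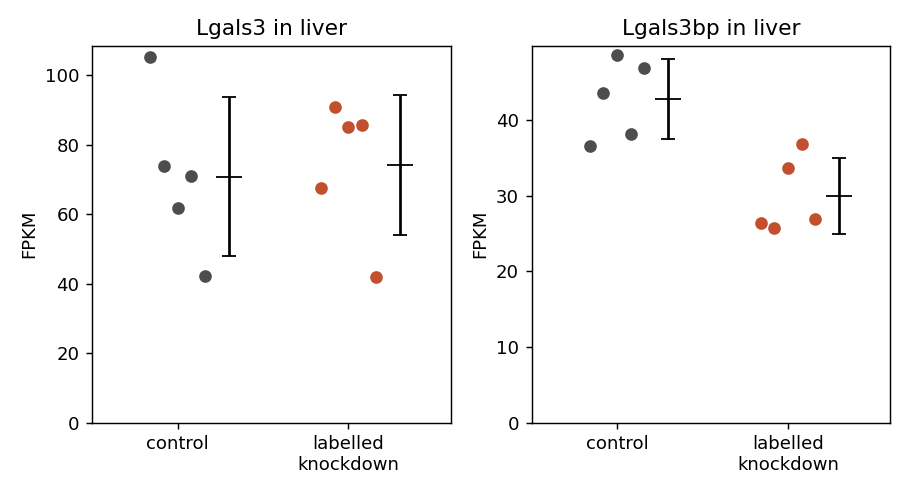
FPKM of Lgals3 and Lgals3bp in each liver library of the control and labelled knockdown groups; points are libraries and the bar beside them is the mean ± SD (n = 5). Lgals3 averaged 70.8 and 74.2 FPKM with overlapping groups, and Lgals3bp averaged 42.7 and 29.9 FPKM.

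The second comparison asked which genes differed between the livers of both groups. The largest changes given here are those among called genes with a mean of at least 1 FPKM, leaving out symbols of Gm and digits, symbols ending in Rik and genes without a symbol; some of the genes left out changed as much. Fgf21, which encodes a hormone released by the liver, rose from 65.6 ± 46.2 to 274 ± 92.8 FPKM (log2 fold change 2.22, SE 0.40, limma adjusted p = 0.00947). Ddit4, an inhibitor of mTORC1 signalling, rose from 12.1 ± 6.82 to 59.5 ± 28.8 FPKM. G0s2, an inhibitor of the lipase that opens lipid droplets, rose from 49.1 ± 36.8 to 161 ± 49.1 FPKM, and Angptl8, a secreted regulator of lipoprotein lipase, from 76.2 ± 51.7 to 230 ± 93.9 FPKM. Rgs16, a regulator of G protein signalling (log2 fold change 2.08), and Hcn3, an ion channel gene (1.67), also rose. Nr1i3, which encodes the nuclear receptor CAR (1.22), and Mir7085, annotated as a microRNA precursor (1.22), rose too. The limma adjusted p of Rgs16, Hcn3, Nr1i3 and Mir7085 lay between 0.00846 and 0.0208. Mir7085 averaged 1.19 ± 0.592 and 4.06 ± 1.13 FPKM, and whether its reads came from that precursor was not tested. Each of these 8 genes was above the control mean in 5 of 5 labelled knockdown libraries. All 8 stayed past the threshold in each of the 10 fits that left out 1 library. Control 1 lay inside the labelled knockdown range for Rgs16 (83.8 FPKM, range from 57.3), Angptl8 (163, from 131) and Hcn3 (4.23, from 4.17). It lay below that range for Fgf21, Ddit4, G0s2, Nr1i3 and Mir7085. Cyp2a22 (log2 fold change 1.41, adjusted p = 0.0260) and Mup-ps16 (1.17, 0.0404) completed the 10 largest increases under this rule; both belong to families of similar genes whose reads could be shared, and their calls held in 6 and 3 of those 10 fits.

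Among the 10 largest decreases under the same rule, 6 were genes of mitosis. Cdc20, an activator of the anaphase-promoting complex, went from 12.0 ± 6.99 to 1.99 ± 1.62 FPKM (log2 fold change -1.95, SE 0.53, limma adjusted p = 0.0300), a call that held in 3 of the 10 fits without 1 library, with an adjusted p of up to 0.0701. Ccnb2, a cyclin of mitosis, fell from 5.15 ± 2.82 to 0.960 ± 0.510 FPKM (log2 fold change -1.52, adjusted p = 0.0162). Ccnb1 (-1.34), the spindle genes Ckap2 (-1.34) and Kif20a (-1.23), and the mitotic kinase gene Pbk (-1.22) fell with limma adjusted p between 0.0116 and 0.0187. D17H6S56E-5 fell from 49.7 ± 20.4 to 10.6 ± 7.59 FPKM (log2 fold change -2.20, adjusted p = 0.0103). Idi1, an enzyme of the isoprenoid pathway, went from 41.0 ± 19.7 to 15.1 ± 7.44 FPKM (log2 fold change -1.32, adjusted p = 0.0449), but its call held in 2 of the 10 fits without 1 library. Idi1-ps1 (-1.46) and Zrsr2-ps1 (-1.41) are pseudogenes that resemble other genes, so their values are uncertain. The Idi1-ps1 call held in 3 of the 10 fits without 1 library, and the Zrsr2-ps1 call in all 10.

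**Figure D2:**
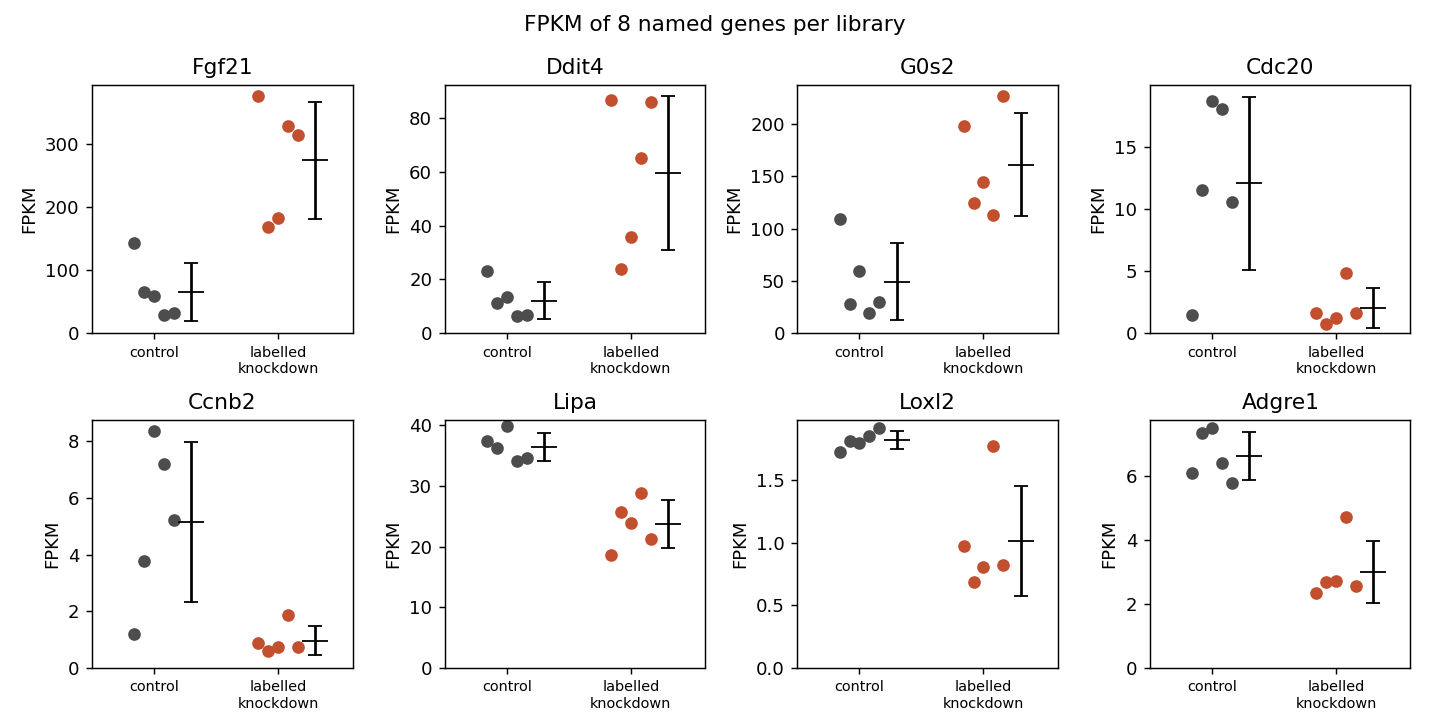
FPKM of 8 named genes in each library of the control and labelled knockdown groups, each panel on its own linear axis starting at 0; points are libraries and the bar beside them is the mean ± SD (n = 5). Fgf21 averaged 65.6 and 274 FPKM and Lipa averaged 36.5 and 23.7 FPKM, and control 1 held 1.41 FPKM of Cdc20 among control libraries of 10.6 to 18.7 FPKM.

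In total, 13471 genes were tested, and 960 were higher and 1300 lower in the labelled knockdown libraries at a limma adjusted p under 0.05, or 16.8% of those tested. Of these, 720 of the higher and 1245 of the lower genes were protein-coding. On the log2(FPKM + 1) scale, 30 and 29 changed at least 2-fold, a scale that understates the change of low genes. The groups did not overlap for 1770 tested genes, 13.1%, where chance gives 0.794%. With median-of-ratios scaling, 1212 genes were higher and 1020 lower. The number of higher genes dropped to 492, 440 and 623 without control 2, 3 or 4, and to 594, 603 and 592 without labelled knockdown 1, 3 or 5; the number of lower genes dropped to 533, 615 and 791 without those controls, and to 826, 830, 751 and 712 without labelled knockdown 1, 2, 3 or 5. The authors' deposited table marked 398 genes as significant, 160 up and 238 down. That mark went with at least a 2-fold change in the ratio of group mean FPKM. Of the 398, 193 were tested here, and 171 passed in the same direction, without a fold threshold.

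Of the 35 gene lists tested, 6 were lower and 1 was higher in the labelled knockdown libraries (camera with a preset correlation of 0.01). Of these, 0 passed with an estimated correlation or with fry in 1 direction. The cell cycle list fell: 16 of 23 tested members were lower and 0 were higher, with a median log2 fold change of -0.71 (adjusted p = 1.25e-08, and 0.786 with an estimated correlation), and 20 were lower when adjusted over the list alone. On the FPKM scale the median log2 ratio of group means was -1.56. Top2a, a topoisomerase of dividing cells, fell from 1.24 ± 0.393 to 0.305 ± 0.119 FPKM, and Mcm5, part of the replication helicase, from 2.36 ± 0.536 to 0.965 ± 0.360 FPKM. Control 1 had a mean list value of 1.36 on the log2(FPKM + 1) scale, where the other control libraries lay between 1.96 and 2.16 and labelled knockdown libraries between 0.951 and 1.503.

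The fibrosis and extracellular matrix list fell, with 13 of 35 tested members lower and 0 higher (median log2 fold change -0.40, camera adjusted p = 7.12e-07, and 0.786 with an estimated correlation), and 20 lower when adjusted over the list alone. Labelled knockdown 4 showed no fall. Its mean list value was 2.82 on the log2(FPKM + 1) scale, inside the control range of 2.66 to 2.96. The other labelled knockdown libraries lay between 1.93 and 2.55. Loxl2, an enzyme that crosslinks collagen, fell from 1.82 ± 0.0695 to 1.01 ± 0.438 FPKM (log2 fold change -0.51, adjusted p = 0.02002). Thbs1, a matrix glycoprotein, fell from 3.36 ± 1.52 to 1.45 ± 0.605 FPKM, and Sparc, a collagen-binding protein, from 26.5 ± 2.64 to 16.6 ± 5.83 FPKM; their calls held in 5 and 4 of the 10 fits without 1 library. Of the 18 tested members of the stellate cell and myofibroblast list, 3 were lower, and its set test gave an adjusted p of 0.504.

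The cholesterol synthesis list fell, with 8 of 24 tested members lower and 0 higher (median log2 fold change -0.53, camera adjusted p = 1.86e-05, and 0.786 with an estimated correlation), and 10 lower when adjusted over the list alone. Control 5 had a mean list value of 3.65 on the log2(FPKM + 1) scale, inside the labelled knockdown range of 3.59 to 4.18. The other control libraries lay between 4.31 and 4.79. Hsd17b7, an enzyme of the pathway, fell from 8.70 ± 1.92 to 5.23 ± 1.20 FPKM (log2 fold change -0.64, SE 0.16, limma adjusted p = 0.0223). Its adjusted p was 0.0540 without control 2. Idi1 is a member of this list too. Control 5 held 13.3 FPKM of it where the other control libraries held 28.3 to 61.2.

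Kupffer cell markers fell as a list, with 2 of 13 tested members lower and 0 higher (median log2 fold change -0.40, camera adjusted p = 0.0298), and 7 lower when adjusted over the list alone. The 2 were Adgre1, which encodes the macrophage antigen F4/80, from 6.63 ± 0.760 to 3.01 ± 0.975 FPKM (log2 fold change -0.95, adjusted p = 0.00684), and Cd5l, a protein secreted by macrophages, from 53.1 ± 14.6 to 25.8 ± 7.08 FPKM. The groups overlapped in the mean value of the list. Its adjusted p was 0.120 without control 3, 0.0631 without labelled knockdown 1, and 0.786 with an estimated correlation. Markers of monocyte-derived and lipid-associated macrophages (median log2 fold change -0.33, adjusted p = 0.0584), cholangiocytes (-0.45, 0.0584) and sinusoidal endothelium (-0.27, 0.0603) did not pass camera, but these results depended on the processing. The macrophage and the cholangiocyte list each passed as lower in 6 of 11 alternative settings and in 5 of the 10 fits without 1 library, and the endothelium list in 3 and 3. Without 1 library at a time their medians ranged from -0.39 to -0.14, -0.54 to -0.21 and -0.36 to -0.20. Markers of T and NK cells gave a median of 0.04 over 9 tested members (adjusted p = 0.590), and those of B and plasma cells 0.04 over 6 (0.510). Only 3 of 14 neutrophil markers were tested, so that list was not.

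The interferon response list fell, with 4 of 29 tested members lower and 0 higher (median log2 fold change -0.21, camera adjusted p = 0.0391, and 0.786 with an estimated correlation). Among them was Ifit2, an interferon-induced antiviral gene, from 1.80 ± 0.331 to 1.03 ± 0.225 FPKM. The Ifit2 call held in each of the 10 fits without 1 library, and those of the other called members in only 3 or 4. The lysosome and autophagy list fell, with 4 of 26 tested members lower and 1 higher (median log2 fold change -0.17, adjusted p = 0.0298, and 0.786 with an estimated correlation). Lipa, the lysosomal acid lipase, fell from 36.5 ± 2.29 to 23.7 ± 3.95 FPKM (adjusted p = 0.00944), while Ctsz, a lysosomal protease, rose from 186 ± 9.14 to 225 ± 16.6 FPKM (adjusted p = 0.0383). The groups overlapped in the mean values of both lists. The Ctsz call held in 6 of 11 alternative settings and in 3 of the 10 fits without 1 library. Adjusted over each list alone, 4 interferon members were lower, and 6 lysosome members were lower and 1 higher. The interferon list lost its call without control 3 or 4 or labelled knockdown 2, 4 or 5 (adjusted p = 0.0958, 0.163, 0.0996, 0.0523 and 0.0643) and with an FPKM minimum of 1 (0.0797), and the lysosome list without control 1 or 4 or labelled knockdown 1 or 5 (adjusted p = 0.0526, 0.0560, 0.0952 and 0.0818) and with array weights (0.0547).

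The list of mitochondrially encoded genes rose, with 13 of 13 members above 0 in log2 fold change and 1 past the test for single genes (median 0.29, camera adjusted p = 0.00510), and 0 adjusted over the list alone. That member, mt-Nd3, a subunit of respiratory complex I, went from 536 ± 124 to 772 ± 145 FPKM (log2 fold change 0.54, limma adjusted p = 0.0415), a call that held in 2 of the 10 fits without 1 library. Mitochondrially encoded genes took 14.2 ± 1.57% of FPKM in the control libraries and 16.4 ± 3.06% in the labelled knockdown libraries, with 21.7% of FPKM in labelled knockdown 1. The list's median ranged from 0.17 without labelled knockdown 1 to 0.36 without control 5. Control 5, with a mean list value of 11.9, lay above 4 of the 5 labelled knockdown libraries. The list gave an adjusted p of 0.786 with an estimated correlation, of 0.164 after each library's trend with transcript length was removed, and of 0.403 with quantile normalization.

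**Figure D3:**
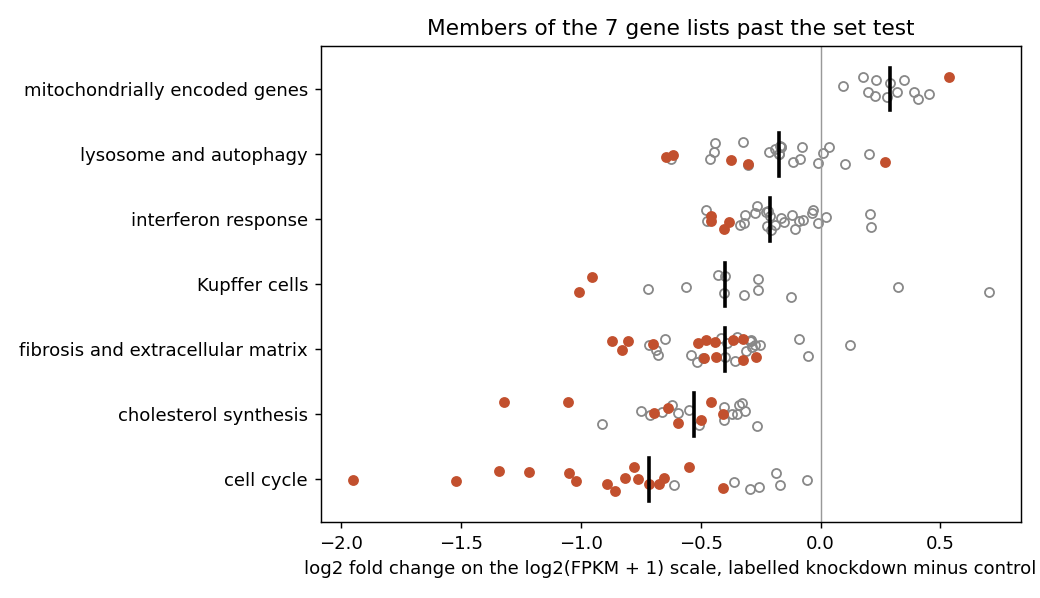
Log2 fold change on the log2(FPKM + 1) scale, labelled knockdown minus control, of each tested member of the 7 gene lists past the set test; filled points passed an adjusted p of 0.05 over all tested genes, open points did not, and black bars are list medians. Cell cycle members had a median of -0.71 and mitochondrially encoded genes a median of 0.29.

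The libraries also differed by transcript length, which moved with the groups and so stands beside every gene group above. Per doubling of transcript length, a library's log2 value departed from the gene mean by 0.03 ± 0.01 in the control group and by -0.03 ± 0.02 in the labelled knockdown group (SD, n = 5), with no overlap between the groups (exact two-sided permutation p = 0.00794, the smallest possible). With tested genes cut into 5 classes of equal size by transcript length, 431 genes of the shortest class were higher and 55 lower, and 54 genes of the longest class were higher and 438 lower. After this trend was removed from each library, 894 genes were higher and 720 lower of 13187 tested; 601 of the 960 higher and 647 of the 1300 lower genes kept their call. The cell cycle, fibrosis, cholesterol, Kupffer cell, lysosome and interferon lists stayed past the set test, with adjusted p of 5.14e-10, 9.86e-08, 4.14e-06, 0.00389, 0.0336 and 0.0325. Their median log2 fold changes became smaller, at -0.66, -0.29, -0.48, -0.37, -0.095 and -0.14. The lysosome, interferon and fibrosis lists shrank most, from -0.17, -0.21 and -0.40.

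**Figure D4:**
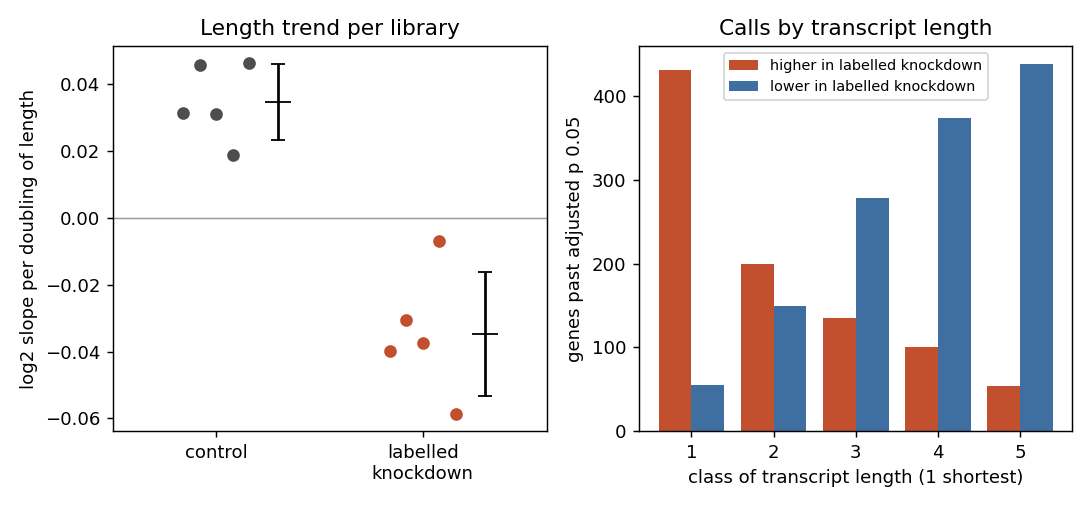
Left, slope of each library's log2 value on log2 transcript length, with the mean ± SD of each group (n = 5); right, number of genes past adjusted p 0.05 in each of 5 classes of transcript length, from 1 for the shortest. All 5 control slopes are above 0 and all 5 labelled knockdown slopes below 0, and 438 of the longest transcripts were lower.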

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

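The gap of the most distant library to its nearest neighbour, set against the range of its group of 5, was checked for 132 groups of values (genes on the log2(FPKM + 1) scale), and 19 were far from the rest; chance gives about 1 in 20. Several of them share a library. Control 1 was low in mitosis transcripts, with Cdc20 at 1.41 FPKM (other control libraries 10.6 to 18.7), Pbk at 0.385, Top2a at 0.572 and a mean of the cell cycle list of 1.36; Ctsz was at 202 FPKM there. Control 5 held Col4a2 at 5.71, Laptm5 at 16.1 and Lgals1 at 21.2 FPKM, below the other control libraries, and mt-Nd3 at 753 FPKM with a mean of the mitochondrially encoded list of 11.9, above them. Control 4 held Thbs1 at 6.03 FPKM, above the other control libraries at 2.31 to 3.06. Fads2 was at 366 FPKM in control 3 (others 230 to 263), and Cps1 at 520 FPKM in control 5 (others 355 to 385).

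Labelled knockdown 1 had 21.7% of its FPKM in mitochondrially encoded genes, where the other labelled knockdown libraries had 14.4 to 16.3%, with mt-Nd3 at 1029 and mt-Co2 at 7784 FPKM and also Cyp2a22 at 43.9 FPKM. Labelled knockdown 4 lay nearer the control group in Adgre1, at 4.73 FPKM against 2.33 to 2.72 in the other 4 labelled knockdown libraries, and in Ccnb1, at 0.645 FPKM against 0.110 to 0.214. Its fibrosis list value, in the report, was also at control level.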

How the results depend on the processing

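The counts of genes, lists and pathway terms, Lgals3, the lists and terms quoted and the genes described were recomputed under the alternatives set before the data were examined and under the FPKM minimum of 1, both scalings, array weights, robust variance and the length and GC trends, which were chosen after seeing the data; alternatives that need read counts were not run. The genes higher and lower numbered 511 and 682 with no filter on low values (29657 genes tested), and 1500 and 2083 at an adjusted p under 0.1. At 2-fold or more on the log2(FPKM + 1) scale they numbered 30 and 29. The lower genes numbered 2047 with array weights, 720 with the length trend removed and 728 with the length and GC trends removed. Calls shared with the authors' deposited table were 108 at an FPKM minimum of 1, which tests fewer genes. Lists higher numbered 0 with quantile normalization, the length trend removed, the length and GC trends removed, an estimated correlation and fry. Lists lower numbered 13 with no filter, 11 with the length trend removed, 10 with the length and GC trends removed, and 0 with an estimated correlation and 0 with fry. The Lgals3 log2 fold change was -0.0063 with the length and GC trends removed. Without 1 library at a time, higher genes ranged from 440 to 954, lower genes from 533 to 1733, lists higher from 1 to 2, and the Lgals3 value from -0.0934 without control 5 to 0.264. Counts fell without control 2, 3 or 4 and without labelled knockdown 1, 3 or 5, whose values stand in the report, and each such fit has fewer libraries; the cause of the other changes was not tested. With the replicate block, 769 genes were higher and 986 lower; the same numbers correlated at 0.114, 0.018, 0.084, -0.015 and 0.050 in their departures from group means, and not every library correlated best with its own number, so the numbers were not taken as pairs. The 49 other genes taken by the naming rule, the 7 lists past the set test, the 8 genes chosen after their values were seen and the 3 quoted pathway terms kept their direction under each alternative run. Of those 49, 24 lost their call with no filter, 8 with the length trend removed and 8 with the length and GC trends removed. Another 5 calls were lost with the replicate block, 3 with each scaling, 1 with robust variance, and 1 to 16 without 1 library at a time. Not every gene was tested in each fit. At an FPKM minimum of 1, 42 of the 49 were tested. Ccnb1, Ckap2, Pbk and Top2a were tested in 5 of the 10 fits without 1 library. Of those 8 genes, Cps1, Fads2, Mlxipl and Leap2 stayed past the threshold throughout; Apoa2 passed in 9 of 11 settings, Cpt1a in 10 of 11, and Ppara in 10 of 11 and in 8 of 10 fits without 1 library. Zfp708 passed wherever it was tested, but fell below the filter at an FPKM minimum of 1 and without any 1 control library. Pathway terms numbered 7 higher and 86 lower with the length trend removed, and 7 and 93 with the length and GC trends removed. Medians of lists that did not pass changed sign around 0: B and plasma cells at -0.0182 and -0.00508 with those trends removed, T and NK cells at -0.0202 with no filter, and hepatocyte functions at 0.0045 with median-of-ratios scaling and 0.0428 with array weights. Without 1 library at a time, these medians ranged from -0.0890 to 0.140, -0.0522 to 0.136 and -0.0722 to 0.0499, and that of lipogenesis from -0.0141 to 0.107.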

Other observations

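Genes of hepatocyte metabolism changed in both directions. The genes of this paragraph were chosen after their values were seen and the lists they belong to did not pass camera in the main fit. The list of fatty acid oxidation and PPARalpha targets passed as lower in 1 of 11 alternative settings and in 1 of the 10 fits without 1 library. In the list of fatty acid oxidation and PPARalpha targets (camera adjusted p = 0.158), Ppara, a nuclear receptor of lipid catabolism, went from 8.88 ± 2.002 to 4.90 ± 1.48 FPKM and Cpt1a, which brings fatty acids into mitochondria, from 48.2 ± 12.2 to 26.5 ± 7.46 FPKM, both called lower, while Fgf21 of the same list was higher; in all, 5 of 30 tested members were lower and 1 higher. In the lipogenesis list (adjusted p = 0.590), 3 members were higher and 3 lower: Mlxipl, a glucose-responsive transcription factor, rose from 47.4 ± 9.14 to 90.7 ± 17.9 FPKM, and the desaturase gene Fads2 fell from 272 ± 54.1 to 127 ± 26.1 FPKM. In the list of hepatocyte functions (adjusted p = 0.857), 5 of 27 tested members were lower and 2 higher; Cps1, an enzyme of the urea cycle, fell from 403 ± 66.7 to 245 ± 30.5 FPKM and Apoa2, an apolipoprotein, rose from 3840 ± 616 to 6047 ± 638 FPKM.

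Of 321 pathway terms in the deposited table, a family tested after the data were seen, camera with the preset correlation placed 13 higher and 146 lower, and 0 passed with an estimated correlation. The Ribosome term had 61 of 143 tested genes higher and 0 lower (median log2 fold change 0.25, adjusted p = 7.53e-19), and Oxidative phosphorylation had 43 of 122 higher and 4 lower (0.23, 3.67e-10). After the length trend was removed their adjusted p was 7.61e-09 and 1.99e-04 and their medians 0.21 and 0.15. The mitochondrial respiratory chain list, fixed before the data were examined, did not pass camera in the main fit. It had 5 of 24 tested members higher and 2 lower (median log2 fold change 0.05, adjusted p = 0.144). With the length trend removed its median was 0.0042 (camera adjusted p = 0.730). It passed as higher without labelled knockdown 1. Leukocyte transendothelial migration had 24 of 80 genes lower and 0 higher (median -0.22, and -0.16 with the length trend removed). Neither the circadian clock list nor that of immediate early and heat shock genes passed camera (adjusted p = 0.590 and 0.104). Of 17 tested clock genes, 1 was higher and 2 lower, or 2 and 5 adjusted over the list alone. Of 17 immediate early and heat shock genes, 3 were lower and 0 higher. That list passed as lower in some alternatives, among them the replicate block (camera adjusted p = 0.0461) and removal of the length trend (0.0336). The cause was not tested.

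The test on non-hepatocyte cells below, and the level of 2 FPKM used with it, were chosen after its result was seen. Lgals3 was not lower in the labelled knockdown libraries. With the mean of the monocyte-derived and lipid-associated macrophage list as a covariate, the group coefficient of log2 Lgals3 was 0.48 (SE 0.18). A hidden decrease was predicted to bring it below 0, which was not seen. That list mean was itself lower in the labelled knockdown libraries, 3.70 ± 0.363 against 4.01 ± 0.223, and adjusting for it raised the coefficient from 0.08. The test therefore cannot exclude a decrease in hepatocytes hidden by macrophage transcripts of that list. A single exchange of libraries between the groups is argued against, since the labelled split separated 1770 tested genes completely and the best of the 25 single exchanges separated 606. Labels exchanged for whole groups would only turn the sign of the log2 difference of 0.08, so they would not account for an unchanged Lgals3. The labels do not describe the insert of the vector, so whether it lowers Lgals3 is not known from them. An effect on protein only stays open and was not tested. A decrease in hepatocytes offset by other cells also stays open: only the macrophage list was used as a covariate, and that test could not exclude it.

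The cell cycle, fibrosis and Kupffer cell lists were lower together. The trend with transcript length does not account for all of this, because the list medians after its removal were -0.66, -0.29 and -0.37 and their set tests still passed, with the reservation that no list passes with an estimated correlation. Fewer non-hepatocyte cells of every type cannot be told apart. The 15 tested T, NK, B and plasma cell genes lay 0.62 above the 35 fibrosis genes in median log2 ratio of group means (bootstrap interval over genes 0.42 to 0.99), but 11 of the 15 averaged under 2 FPKM in the control libraries, too near the floor to exclude it. On the same scale the medians of cholangiocyte (-0.58), sinusoidal endothelium (-0.46), Kupffer cell (-0.41) and monocyte-derived macrophage (-0.36) markers lay nearer the fibrosis median of -0.56, and that of stellate cell and myofibroblast markers was -0.16. The 6 tested dendritic cell markers went both ways (median -0.07): Batf3 was called higher, from 0.700 to 1.42 FPKM, which goes against fewer cells of every type, but is also near the floor. Fewer dividing and matrix-producing cells, lower transcript levels per cell, and a difference in RNA integrity between the groups may each contribute, and none of these was tested. Of 100 splits of the 10 libraries, 1, the labelled split, gave as many genes past the threshold. It gave 2260, and the highest of the others gave 25. A share of 1 in 100 was the smallest this test could give, and the size of the gap does not lower it. Chance is therefore unlikely for that count but not excluded. A technical difference that moves with the groups is not excluded either.

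Zfp708, a zinc finger gene singled out after its values were seen, stood at 0.734 to 1.45 FPKM in the control libraries, and was listed at 0 in labelled knockdown 1, 2 and 5 and at 0.0103 and 0.0227 FPKM in labelled knockdown 3 and 4. Together with 7 other genes, among them Zrsr2-ps1, Leap2 and Fads2, it separated the groups by at least 0.5 on the log2 scale, a gap chosen after the largest gaps had been seen, so the set of 8 genes and the close-pair test below rest on that choice. Whether reads moved to a similar gene cannot be told. Of the other tested zf-C2H2 genes, 12 passed the test and gained at least the 1.17 FPKM that Zfp708 lost. These genes were taken by family, not by likeness to the Zfp708 sequence. Of the 353 zf-C2H2 genes 5.10% were higher, against 7.13% of all tested genes, so such gains were likely without moved reads. A genetic difference between both sets of mice cannot be told apart: the 6 placed genes formed 0 close pairs, a share of 1 of random lists gave at least as many, and most random lists also gave 0, so the test could not have excluded it.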
